A study of Mus musculus with 42 samples.

How the data were processed

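Bulk RNA sequencing was analysed for 42 mouse libraries in 12 groups. Of these, 18 came from tumours that grew after organoids were injected into the colon or rectum, 22 from cultured tumour organoids and 2 from primary small-intestinal tumours. Per the labels' protocols, tumour pieces were stored in RNAlater and organoids were frozen as pellets. RNA was extracted with the RNeasy Mini Kit and libraries were made with the TruSeq RNA LT kit and sequenced on a NextSeq 500 in pairs of 36 cycles. Wild-type colon tissue, which the series text also mentions, was not analysed here.

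The values are raw counts per Ensembl gene as deposited by the authors, without scaling, in 1 table for the transplanted tumours and 1 table for the organoids and primary tumours. Each table was a batch of its own, per the labels. FastQC 0.11.8, Trim Galore 0.6.4, HISAT2 2.1.0 and featureCounts 1.6.4 were named with build GRCm38, per the submitters' processing notes, which gave no role or order for them. The annotation release, the strand setting and the treatment of reads with several matches are not given in the sources used here. Counts of genes with near-identical copies, such as the alpha-defensins, and of overlapping or antisense genes are therefore uncertain. Symbols and coordinates were looked up by identifier in GENCODE mouse release 21, which is on GRCm38. A symbol was found for 55154 of the 55421 identifiers in each table, and identifiers without a symbol held 0.00254% of the counts in the tumour table and 0.002% in the organoid table. Every row named a gene, and no column of values was left without a sample.

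Groups were taken from the sample titles. Samples of the 2 tables were never tested against each other. Within a table, counts were filtered with filterByExpr by group, scaled with TMM factors and tested with the quasi-likelihood F test of edgeR 4.0.16 (robust fit) in R 4.3.3, with limma 3.58.1. P-values were adjusted by the method of Benjamini and Hochberg over the genes tested, and a gene was called at an adjusted p under 0.05. The 10 comparisons and their models were fixed before the data were examined. The AKPS tumour comparisons were fitted on all 18 transplanted tumours and the organoid comparisons on all 22 organoid libraries, so that groups of 2 or 3 shared an estimate of the spread. The comparison of liver-metastasis with small-intestinal origin in KPN tumours used 11 tumours with the organoid line as a covariate, because each line name occurred with both origins. The library labelled RKAC.2f was left out there, since that name matched neither RKAC3.2f nor RKAC13.1e exactly. The primary tumours were compared with organoids in a fit of those 6 libraries. Levels are given as CPM, counts scaled to the total count of the library without the TMM factor, as mean ± SD over the libraries of a group.

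Gene lists, 42 in number, were fixed before any count was seen and cover signalling pathways, epithelial cell types, regional identity and the stromal and immune cells that a tumour piece could hold. A list was tested when at least 5 members were measured, with adjustment over the lists of a comparison. The test was camera on the filtered counts and dispersions of the edgeR fit, at a preset inter-gene correlation of 0.01. Camera with an estimated correlation and fry were run as alternatives. The fry test asks whether the members move, on balance, one way, and does not compare them with other genes. Counts of called members are given over all genes tested and adjusted over the list alone. Named genes followed a fixed rule. In each of the 5 main comparisons it took the 8 most raised and the 8 most lowered called genes with a mean of at least 8 CPM in the higher group and no overlap between the libraries of the groups, and 4 and 4 in the other comparisons. Predicted or unnamed genes, Rik clones, pseudogenes, immunoglobulin and T cell receptor segments, histone and ribosomal protein genes and sex genes were left out of this part. For each list described, it took up to 3 called members per direction by p-value, or the 2 members with the highest CPM where none was called. The engineered genes and Il6, Il11, Lif, Osm and Tgfb1 were always included. The text names part of the genes so chosen.

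Where every library of a group had a count of 0, a fold is given as a lower bound against a floor of 3 counts over the whole group. With 1 to 3 counts in a group, the ratio of pooled CPM is given with its exact 95% counting interval. Such floors and intervals cover counting error only, since reads without molecular identifiers are not independent molecules. Fitted log2 values of such genes depend on the prior count and are not printed as bounds. Median total counts were 20589862 per tumour library and 15680071 per library of the organoid table.

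The alternatives were DESeq2 1.42.0 as a test and DESeq2 size factors in the edgeR test, no low-count filter, a filter at 5 CPM, a block on the replicate number, fits on only the 2 groups compared, each line alone, the labelled sex as a covariate or within sex, and leaving out each library in turn. An adjusted p that DESeq2 gave as NA stayed NA. Alternatives without pairs of libraries that stood apart, and the comparison between the 2 KPN lines, were chosen after seeing the data. Each comparison was tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold. The edgeR test called 19% of the 2-fold and 59% of the 4-fold changes in the simulated AKPS against KPN tumours, with 3 false calls. DESeq2 called 40% and 72% with 64 false calls in a separate simulation, so the tests cannot be compared. For the 2 origins the edgeR test called 18% and 77% in simulated KPN tumours and 14% and 49% in simulated KPN organoids. For the AKPT against KPN organoids the shares were 17% and 48%, and for the primary tumours against organoids 2% and 24%.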

Results

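Gene expression was measured in mouse intestinal tumours and in organoids, which are tumour epithelium grown in culture. The tumours carried combinations of alleles switched by a villin-driven CreER recombinase, which acts in the intestinal epithelium. The letters of a genotype name a floxed Apc (A), an activated Kras (K), a floxed Trp53 (P), a floxed Smad4 (S), a floxed Tgfbr1 (T) and a Notch1 transgene (N). The transplanted tumours comprised 6 colon tumours from KPN liver-metastasis organoids, 6 colon tumours from KPN small-intestinal tumour organoids, and 3 colon and 3 rectal tumours from AKPS small-intestinal tumour organoids, all in male mice. The second table held organoids from small-intestinal tumours (2 Apc, 2 AKPS, 4 AKPT and 5 KPN), from KPN liver metastases (4) and from colon tumours (3 AK and 2 AKP), with 2 AKPT primary small-intestinal tumours. Total counts were 8307206 to 24765688 per transplanted tumour and 7815940 to 18169260 per library of the second table. AKPS tumours came from 1 organoid line and KPN tumours, bar 1 labelled RKAC.2f, from 2 lines. The labels gave no animal for organoids, so p-values measured spread between tumours or cultures. No 2 libraries of a group were as close as sampling noise alone would make them.

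The engineered genes were examined first as a check of the labels. Trp53, which encodes the tumour suppressor p53, averaged 223 ± 8.03 CPM in Apc organoids (SD, n = 2) and 131 ± 9.25 in AK organoids (n = 3), the groups with intact Trp53. It lay at 9.57 ± 3.07 CPM in KPN small-intestinal organoids (n = 5), 9.43 ± 4.32 in KPN liver-metastasis organoids (n = 4) and 6.41 and 6.67 in the AKPS organoids. The AKP organoids had 24.9 and 6.45 CPM. In the AKPT organoids 3 libraries had 8.75 to 10.7 CPM, but replicate 3 had 91.3, against its label. Smad4, the shared mediator of TGF-beta signals, was at 22.5 ± 0.879 CPM in AKPS organoids (n = 2) against 137 ± 39.5 in KPN and 157 ± 19.6 in AKPT organoids. In colon tumours from small-intestinal organoids Smad4 was at 56.1 ± 13.7 (AKPS) against 126 ± 22 CPM (KPN), and 61.4 ± 32.6 in AKPS rectal tumours. Notch1 averaged 210 ± 125 CPM in KPN small-intestinal organoids, but replicate 5 had 6.65 and the other 4 had 184 to 332. KPN liver-metastasis organoids 1 and 2 had 91.4 and 77.1, near AKPT (71.7 ± 9.03) and AKP organoids (93.6 and 69.9). Organoids 3 and 4 had 188 and 228. Tgfbr1 was at 65.1 ± 3.13 CPM in AKPT and 67.4 ± 15.9 in Apc organoids and was not called, nor was Apc between these groups. Apc is not floxed in KPN organoids by their labels. It was at 39.6 and 20.2 CPM in KPN small-intestinal organoids 4 and 5 against 123 to 193 in the other 3. Organoid 5 was also low in Kras (91.2 against 167 to 220 CPM) and had fewer genes detected (19300 against 23431 to 24427). Its low Notch1 and Apc therefore need not reflect the alleles. Xist and Y-linked genes followed the labelled sex except in KPN liver-metastasis organoids 1, 2 and 4 and KPN small-intestinal organoid 2, labelled male, which had at most 0.0612 CPM of Ddx3y and at most 1.1 CPM of Xist.

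**Figure D1:**
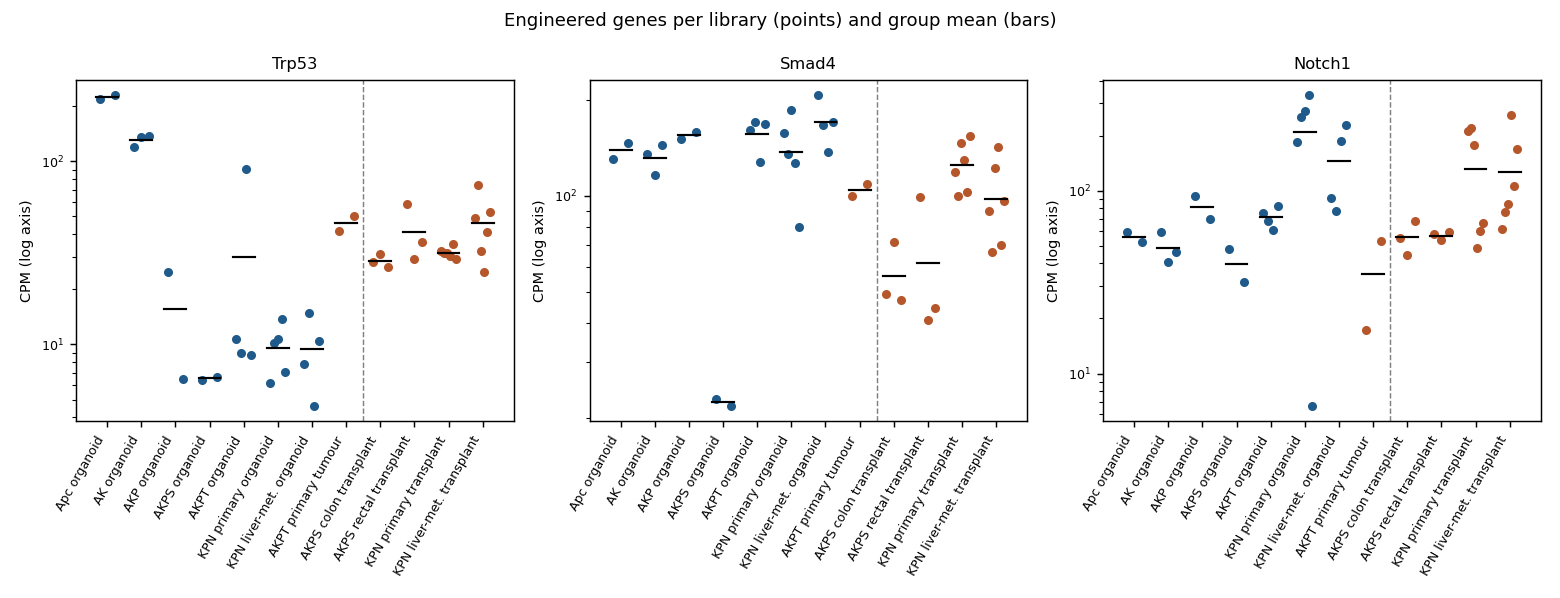
CPM of Trp53, Smad4 and Notch1 (log axes) in every library, with bars at the group means; the dashed line parts the organoid table (left, with the AKPT primary tumours) from the separately scaled tumour table (right), blue marks organoids and orange marks tumours. Trp53 was at 91.3 CPM in AKPT organoid 3 and Notch1 at 6.65 CPM in KPN small-intestinal organoid 5, each apart from its group.

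Whether tumours seeded by metastasis-derived and by primary-site cells differ was addressed in KPN colon tumours of liver-metastasis origin (n = 5) and small-intestinal origin (n = 6). Only Ly6c1, for a surface protein of monocytes and endothelial cells, passed the test. It is also on the fixed YAP and fetal-like epithelial list. It rose to 147 ± 115 from 52.9 ± 40.7 CPM (SD), a log2 difference of 1.77 ± 0.17 (SE, edgeR adjusted p = 0.0118). Within line RKAC3.2f it was at 229 and 310 CPM against 63.4 to 120, and within RKAC13.1e at 57.2 to 72.3 against 17.5 to 21.4. Ly6c1 (ENSMUSG00000079018) lies on chromosome 15 at 75044018 to 75048830 (GRCm38), beside the closely similar Ly6c2, so its count is uncertain. It fell outside the rule for named genes and was chosen after its values were seen. The gp130 cytokines Il6, Il11 and Lif were not called. Il11, a fibroblast cytokine of the IL-6 family, averaged 39.1 ± 48.7 against 13 ± 9.93 CPM (adjusted p = 0.689), Il6 12.3 ± 22.4 against 5.48 ± 7.10 (adjusted p = 0.75) and Lif 103 ± 59.0 against 74.8 ± 26.2 (adjusted p = 0.653).

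No member of the lists described below was called, while 9 of 41 lists passed camera at the preset correlation and 0 with an estimated correlation. MHC and antigen-presentation genes had a median log2 difference of 1.19 (camera adjusted p = 3.81e-07; adjusted p = 0.929 with an estimated correlation), with Cd74, the invariant chain of class II, at 1760 ± 1660 against 866 ± 674 CPM. Interferon-response genes had a median of 0.90 (camera adjusted p = 0.000178; adjusted p = 0.929 with an estimated correlation), with Gbp2 at 186 ± 156 against 103 ± 49.2 CPM. Smooth muscle genes had a median of 1.26 (camera adjusted p = 5.64e-07; adjusted p = 0.903 with an estimated correlation), and 6 of 12 members were higher adjusted over the list alone. Fibroblast genes (median 0.91, camera adjusted p = 0.0452), endothelial genes (1.10, 0.000793) and macrophage and monocyte genes (0.79, 0.0045) lay in the same direction, with adjusted p of 0.933, 0.929 and 0.929 with an estimated correlation. In the other direction lay the mitochondrially encoded genes (median -0.87, camera adjusted p = 5.08e-08; adjusted p = 0.903 with an estimated correlation), the intestinal stem cell genes (-0.36, 0.0172; adjusted p = 0.492 with an estimated correlation) and the MAPK output genes (-0.25, 0.0198; adjusted p = 0.929 with an estimated correlation). Adjusted over the list alone, 2 stem cell genes were lower. Beyond these and the smooth muscle genes, no member of a list named here was called adjusted over the list alone. The libraries differed in stroma, and the lists were not tested without any of them. Liver-metastasis tumour replicate 2 had 17100 CPM of Col1a1, a fibrillar collagen, and 224 of Epcam, an epithelial surface protein, against 1210 to 9570 and 632 to 1610 in the other 5, and 1470 to 7450 and 696 to 1610 in the tumours of small-intestinal origin.

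The edgeR test called 1 gene of 17805 with 2729 at an unadjusted p under 0.05, and DESeq2 called 426 (200 higher, 226 lower). The count was 0 without small-intestinal-origin tumour 1, 2, 3 or 5 or liver-metastasis-origin tumour 4 or 5, 5 without liver-metastasis-origin tumour 2 and 228 (73 higher, 155 lower) without liver-metastasis-origin tumour 3. A test of the product of origin and line asked whether the origin difference depended on the line. It called only Mcpt8, a mast cell and basophil protease on chromosome 14 at 56082166 to 56085273, also named after its values were seen. Mcpt8 was at 35.8 to 71.9 CPM in liver-metastasis-origin tumours of RKAC13.1e against 2.17 to 3.89 in small-intestinal-origin tumours of that line, and at 26.7 and 28.1 against 71.9 to 120 in RKAC3.2f (log2 5.80, adjusted p = 0.019). Among the 17805 genes, 1682 had an unadjusted p under 0.05 for this term, and DESeq2 called 283.

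AKPS and KPN colon tumours, both from small-intestinal tumour organoids, were compared next. Pla2g2a, a secreted phospholipase of Paneth cells, the antimicrobial cells of small-intestinal crypts (ENSMUSG00000058908, chromosome 4, 138831857 to 138835186), averaged 490 ± 44.1 CPM in AKPS tumours (n = 3) against 0.763 ± 1.80 in KPN tumours (n = 6), a log2 difference of 9.29 ± 1.56 (SE, edgeR adjusted p = 0.00124). Pla2g2a is annotated as a polymorphic pseudogene, so its level may follow an allele of the line, which was not tested. Krt14, a keratin of squamous epithelium, fell to 6.74 ± 4.97 from 654 ± 185 CPM (log2 -6.62 ± 0.79, adjusted p = 8.64e-05). Krt5, its partner keratin of basal cells (ENSMUSG00000061527, chromosome 15, 101707070 to 101712898), averaged 620 ± 647 CPM in KPN tumours and had 3 counts in all AKPS colon tumours, a ratio of 13100 with a 95% counting interval of 4490 to 63700. Its KPN level was 1140 to 1280 CPM in RKAC13.1e and 11.2 to 42.5 in RKAC3.2f tumours.

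Of 16 measured Paneth cell genes 13 rose and none fell (15 rose adjusted over the list alone). Their median log2 difference was 7.44, or 6.57 with the 6 members that had no count in a group at their bound (camera adjusted p = 1e-16, and adjusted p = 0.0304 with an estimated correlation). Itln1, an intestinal lectin, averaged 135 ± 36.6 against 0.0996 ± 0.136 CPM. The alpha-defensin Defa24 averaged 67.3 ± 45.7 CPM against 1 count in the 6 KPN tumours, a ratio of 9470 (1700 to 374000), uncertain because alpha-defensin copies are nearly identical. Among the other genes that rose most were Lgals2, a galectin (315 ± 35.5 against 1.02 ± 0.41 CPM), and the genes of gastric surface mucosa Gkn1 (99.5 ± 63.6 against 0.246 ± 0.222) and Anxa10 (124 ± 45.3 against 0.322 ± 0.303). Of 19 intestinal stem cell genes 9 rose (11 adjusted over the list alone), with camera adjusted p = 1.65e-08 and adjusted p = 0.0578 with an estimated correlation. Smoc2, a matrix protein of crypt-base cells, was at 868 ± 262 against 53.5 ± 14.6 CPM, and Hopx, a marker of reserve stem cells, at 77.6 ± 8.68 against 6.88 ± 3.89.

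Of 21 WNT target genes 8 rose and 1 fell (9 and 1 adjusted over the list alone; camera adjusted p = 2.44e-07, adjusted p = 0.166 with an estimated correlation). Ephb2, a receptor of the crypt base, rose by 3.58 ± 0.35 on the log2 scale to 292 ± 10.3 CPM (adjusted p = 2.13e-05), and Nkd1, a feedback inhibitor of WNT signals, by 4.53 ± 0.49 to 254 ± 78.2. Cd44, a hyaluronan receptor, fell from 1890 ± 195 to 583 ± 60.8 CPM. Apc itself was higher in AKPS tumours (192 ± 34.6 against 96.2 ± 14.8 CPM, adjusted p = 0.0158). Notch target genes went down, 6 of 16 (9 lower and 2 higher adjusted over the list alone), with camera adjusted p = 0.000882 and adjusted p = 0.0304 with an estimated correlation. Nrarp, a feedback inhibitor that Notch induces, was at 5.37 ± 0.931 against 48.4 ± 7.16 CPM, and the Notch ligand Jag1 at 51.6 ± 2.13 against 154 ± 66.2. Notch1, on the Notch list, was not called (56.0 ± 12.1 against 131 ± 80.6 CPM, adjusted p = 0.141), and was at 178 to 219 CPM in RKAC13.1e and 48.8 to 66.3 in RKAC3.2f tumours.

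Of 18 TGF-beta ligands and receptors 5 fell (5 adjusted over the list alone; camera adjusted p = 0.00063, adjusted p = 0.198 with an estimated correlation). The list includes Smad4, deleted by design. Tgfb1, the main ligand, was at 75.0 ± 10.9 against 182 ± 48.7 CPM (log2 -1.31 ± 0.26, adjusted p = 0.00427). Ltbp1, which holds latent TGF-beta in the matrix, was at 31.5 ± 9.45 against 140 ± 25.9. Of 20 TGF-beta target genes 4 fell and 1 rose, equally adjusted over the list alone (camera adjusted p = 0.0114; adjusted p = 0.481 with an estimated correlation). The inhibitor Smad7 fell from 80.4 ± 15.9 to 30.3 ± 9.45 CPM and Id2 from 127 ± 30.7 to 50.0 ± 2.92, but Itgb6, an integrin, rose from 14.4 ± 9.78 to 53.1 ± 15.4. Among the genes that fibroblasts express in response to TGF-beta 8 of 24 fell (15 lower and 2 higher adjusted over the list alone; camera adjusted p = 0.000166, adjusted p = 0.479 with an estimated correlation), with fibronectin, Fn1, at 1320 ± 570 against 5520 ± 1910 CPM. Il11 in that list stood the other way, at 86.5 ± 50.4 against 13 ± 9.93 CPM, uncalled (log2 2.72 ± 0.98, adjusted p = 0.0805). Epcam was at 2200 ± 126 against 1090 ± 313 CPM and Col1a1 at 927 ± 122 against 3770 ± 2450. Less stroma may explain falls of stromal genes. Of 15 gp130 cytokines and receptors 3 fell (5 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.0142, adjusted p = 0.481 with an estimated correlation). Clcf1, an IL-6 family cytokine, was at 29.3 ± 5.14 against 124 ± 70.2 CPM and the oncostatin M receptor Osmr at 43.6 ± 14.4 against 144 ± 76.8. Lif (30.0 ± 5.06 against 74.8 ± 26.2 CPM, adjusted p = 0.0537) and Il6 (3.45 ± 2.50 against 5.48 ± 7.10, adjusted p = 0.767) were not called.

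Inflammatory cytokines and chemokines had 2 of 22 members lower and 1 higher (3 and 1 adjusted over the list alone; camera adjusted p = 0.0228, adjusted p = 0.69 with an estimated correlation). Csf3, the granulocyte colony-stimulating factor, fell from 48.0 ± 17.7 to 2.22 ± 1.15 CPM, and the adhesion gene Icam1 rose from 44.8 ± 6.83 to 86.4 ± 21.3. Squamous epithelial genes fell in 6 of 19 members (9 adjusted over the list alone; camera adjusted p = 1.13e-05, adjusted p = 0.166 with an estimated correlation). Goblet cell genes rose in 4 of 18 (6 adjusted over the list alone; camera adjusted p = 1.13e-05, adjusted p = 0.481 with an estimated correlation). Small-intestine regional genes rose in 3 of 13 (4 adjusted over the list alone; camera adjusted p = 0.000228, adjusted p = 0.1 with an estimated correlation). Proliferation genes rose in 4 of 24 (6 adjusted over the list alone; camera adjusted p = 0.000228, adjusted p = 0.69 with an estimated correlation). Examples were Creb3l1, a secretory-cell factor (267 ± 24.9 against 40.9 ± 24.2 CPM), the small-intestinal factor Gata5 (94.5 ± 24 against 1.29 ± 0.586) and the mitotic kinase Plk1 (134 ± 15.3 against 39.5 ± 13). General epithelial genes rose in 3 of 15 (3 adjusted over the list alone; camera adjusted p = 0.000243, adjusted p = 0.579 with an estimated correlation), among them the intestinal factor Cdx2 (106 ± 7.45 against 6.83 ± 5.28 CPM). Fibroblast genes fell in 2 of 24 (2 adjusted over the list alone; camera adjusted p = 0.00759, adjusted p = 0.69 with an estimated correlation). Mesothelial genes fell in 2 of 13 (7 adjusted over the list alone; camera adjusted p = 0.00169, adjusted p = 0.316 with an estimated correlation). The proteoglycan Lum was at 3.67 ± 2.26 against 184 ± 104 CPM and the mesothelial factor Wt1 at 0.154 ± 0.218 against 12.2 ± 7.51.

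In all, edgeR called 1377 genes higher and 1160 lower in AKPS tumours of 20391 tested, 969 and 922 of them by at least 2-fold. Of the called genes 2463 had no overlap between the groups, and of all genes 5392, where chance gives 2.38% of the genes tested. Markers of colon mucosa stood apart in 2 libraries, with the colon regional genes at 4.07 in AKPS colon tumour 2 and 4.72 in KPN tumour 3 (mean log2 of CPM + 1) against 0.97 to 2.59 in the other 7. Without these libraries the counts were 1062 and 500, a share of 68.0% higher, and against tumours of line RKAC13.1e alone 1489 genes were called in all. Leaving out AKPS colon tumour 1, 2 or 3 gave 1473, 1225 or 1085 genes.

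**Figure D2:**
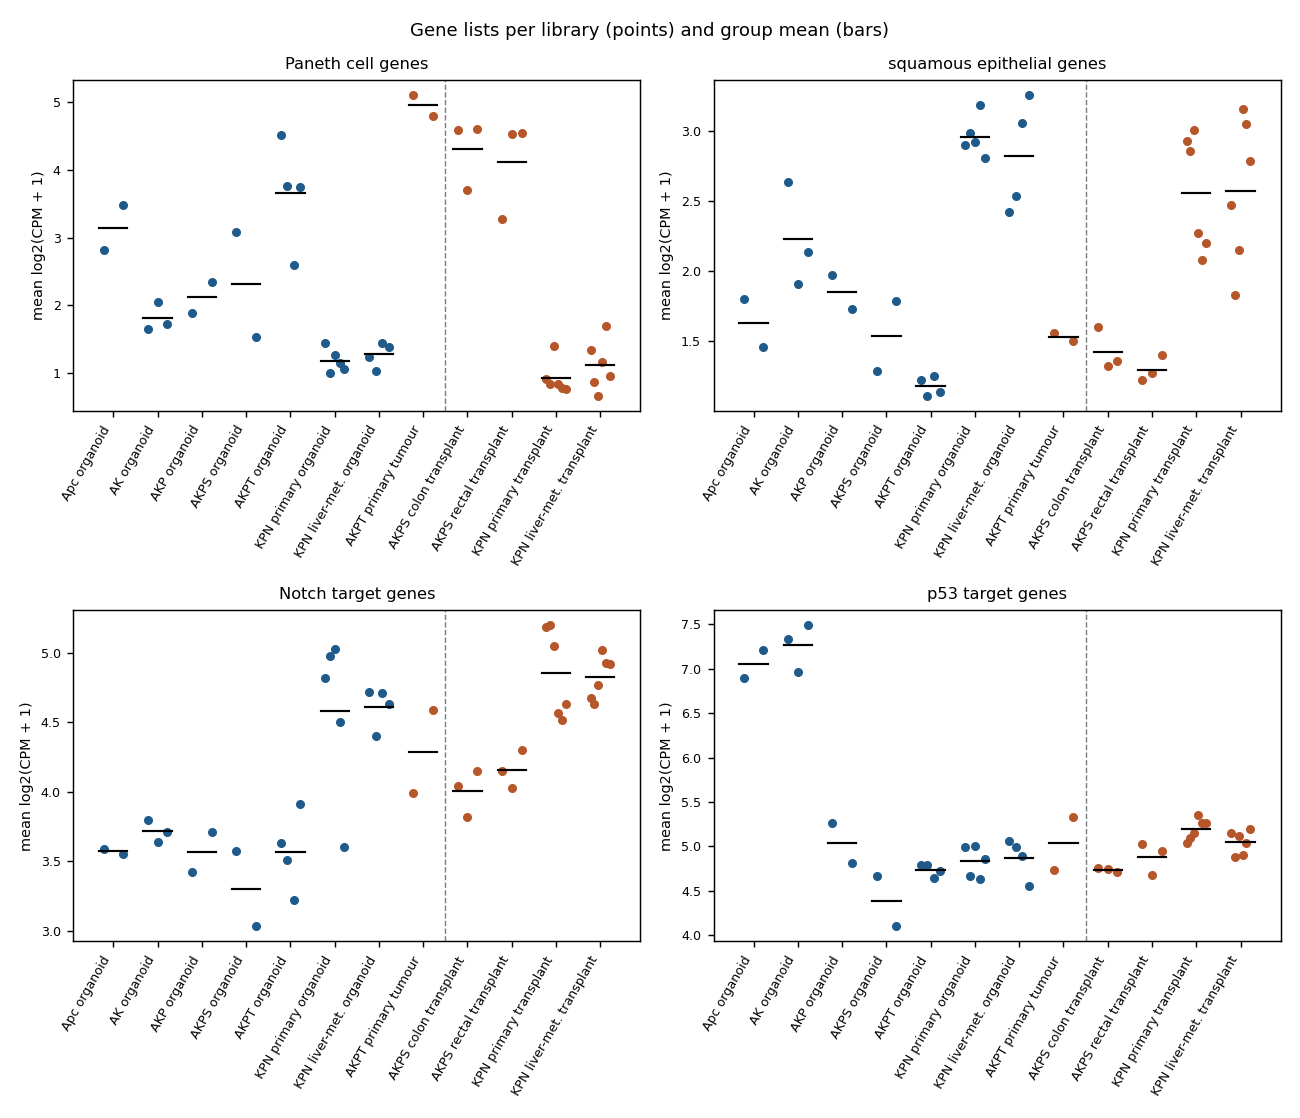
Mean log2(CPM + 1) of the Paneth cell, squamous epithelial, Notch target and p53 target lists in every library, with bars at the group means; left of the dashed line lies the organoid table with the AKPT primary tumours, right the tumour table. The p53 target genes lay at 6.90 to 7.49 in the Apc and AK organoids, above all other libraries.

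Rectal and colon AKPS tumours (n = 3 each) were compared to ask whether the injection site mattered. No gene passed the test. Il11 was at 5.82 to 6.98 CPM in the rectal and 43.4 to 142 in the colon tumours, without overlap but uncalled (log2 -3.76 ± 1.31, adjusted p = 1). Of 20391 genes 1859 had no overlap, where chance gives 10%. Macrophage and monocyte genes had a median log2 difference of 1.15 towards the rectum (camera adjusted p = 1.67e-07; adjusted p = 0.47 with an estimated correlation), with Apoe, a lipid carrier, at 1490 ± 1020 against 730 ± 149 CPM. Fibroblast genes (median 1.04, camera adjusted p = 4.01e-07), smooth muscle genes (1.41, 4.6e-06) and interferon-response genes (0.74, 3.11e-07) lay likewise higher in the rectum, with adjusted p of 0.536, 0.47 and 0.47 with an estimated correlation. Col1a1 was at 2000 ± 528 against 927 ± 122 CPM. Smad4 and Trp53, deleted by design in the tumour cells, were at 99.0 and 58.6 CPM in rectal tumour 1, against 40.8 and 44.5 (Smad4) and 29.2 and 36.2 (Trp53) in rectal tumours 2 and 3. Adjusted over the list alone, 2 fibroblast and 2 smooth muscle genes were higher and no macrophage or interferon gene was called. Proliferation genes lay lower (median -0.54, camera adjusted p = 9.32e-17; adjusted p = 0.388 with an estimated correlation), as did intestinal stem cell genes (-0.21, 0.00659; adjusted p = 0.47 with an estimated correlation), with 0 members called in either list. In all 20 of 42 lists passed camera and 0 with an estimated correlation. By edgeR 571 genes had an unadjusted p under 0.05, and DESeq2 called 0 with 935. Without rectal tumour 2 edgeR called 7 genes, and in a fit of only these groups 1.

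The origin comparison was repeated in KPN organoids, where liver-metastasis cultures (n = 4) were set against small-intestinal tumour cultures (n = 5). No gene passed the test. Lif, a gp130 cytokine that these epithelial cultures expressed, was at 45.0 ± 19.5 against 30.7 ± 25.6 CPM (log2 0.51 ± 0.50, adjusted p = 0.818), and Tgfb1 at 102 ± 41.5 against 108 ± 48.1 (adjusted p = 0.957). Il11 was at most 0.452 CPM in any of the 9 libraries. MHC and antigen-presentation genes had a median log2 difference of -1.45 (camera adjusted p = 0.00147; adjusted p = 0.99 with an estimated correlation), with none of 16 called. Their level was 4.70 in KPN small-intestinal organoid 3 against 2.80 to 2.97 in the other 4, and interferon-response genes stood at 5.43 there against 1.27 to 2.36. WNT target genes (median -0.66, camera adjusted p = 0.0119) and hypoxia and glycolysis genes (0.33, 0.00898) had no called member either, adjusted over the list alone included, and adjusted p = 0.99 with an estimated correlation for both. Ldha, the lactate dehydrogenase of glycolysis, was at 1930 ± 658 against 1700 ± 528 CPM. Among 18458 genes edgeR called 0, with 1354 at an unadjusted p under 0.05 and a lowest adjusted p of 0.335, while DESeq2 called 27 higher and 9 lower with 1677 at an unadjusted p under 0.05. Without liver-metastasis organoid 3 edgeR called 14. Some cultures lay closest to one of the other origin: across genes, which are not independent, liver-metastasis culture 3 correlated with small-intestinal culture 1 at r = 0.986 and culture 4 with culture 2 at r = 0.979, where the mean with the own group was 0.857 to 0.945. Liver-metastasis cultures 1 and 2 correlated at r = 0.985. No animal was given, and the test took the 9 cultures as independent.

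AKPT and KPN organoids from small-intestinal tumours differed widely. Squamous epithelial genes were lowered in AKPT cultures (n = 4) against KPN cultures (n = 5), and of 41 lists this was the only one called by camera with an estimated correlation (adjusted p = 0.0418). Smoc2, the crypt-base matrix protein (ENSMUSG00000023886, chromosome 17, 14279506 to 14404790), rose by 10.51 ± 0.82 on the log2 scale, to 421 ± 159 from 0.225 ± 0.15 CPM (edgeR adjusted p = 1.04e-06). Krt14 (ENSMUSG00000045545, chromosome 11, 100203162 to 100207548) fell by 9.57 ± 1.15, from 927 ± 461 to 1.42 ± 0.382 CPM (adjusted p = 5.84e-05), and Krt5 from 430 ± 380 to 0.159 ± 0.199. Tgfb1 fell from 108 ± 48.1 to 20.3 ± 7.28 CPM (log2 -2.67 ± 0.54, adjusted p = 0.00318) and Lif from 30.7 ± 25.6 to 10.3 ± 2.92 (log2 -1.80 ± 0.53, adjusted p = 0.0307).

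Paneth cell genes rose in 11 of 15 members (11 adjusted over the list alone). Their median log2 difference was 6.68, or 6.32 with the 3 members without a count in a group at their bound (camera adjusted p = 2.17e-11; adjusted p = 0.118 with an estimated correlation). Pla2g2a was at 446 ± 271 against 0.258 ± 0.161 CPM and Lyz1, the Paneth cell lysozyme, at 212 ± 178 against 0.0736 ± 0.0515. Enteroendocrine cell genes split, with 12 of 18 raised and 2 lowered (the same counts adjusted over the list alone; camera adjusted p = 4.5e-05, adjusted p = 0.214 with an estimated correlation). Reg4, a secreted lectin, rose from 1.72 ± 3.06 to 345 ± 254 CPM, while Tph1, which makes serotonin, fell from 184 ± 218 to 0.886 ± 0.973. Goblet cell genes rose in 6 of 17 (9 adjusted over the list alone; camera adjusted p = 3e-05, adjusted p = 0.214 with an estimated correlation). Atoh1, the factor that sets the secretory fate, averaged 4.67 ± 3.39 CPM in AKPT cultures and had no count in KPN cultures, so it was at least 117-fold higher.

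Stem cell genes moved in both directions, with 5 of 19 raised and 1 lowered (the same adjusted over the list alone; camera adjusted p = 3.9e-06, adjusted p = 0.135 with an estimated correlation). Ascl2, a stem-cell factor and WNT target, rose from 0.386 ± 0.391 to 51.4 ± 12.7 CPM, and Olfm4, a stem-cell glycoprotein that Notch induces, fell from 15.7 ± 9.97 to 2.33 ± 2.00. WNT target genes rose in 5 of 21 and fell in 1 (the same adjusted over the list alone; camera adjusted p = 0.000123, adjusted p = 0.466 with an estimated correlation). Ephb2 was at 279 ± 17.3 against 14.5 ± 13.2 CPM, and Cd44 fell from 1190 ± 551 to 241 ± 49.3. Among the most raised genes outside the lists were Igfbp1, a binding protein of insulin-like growth factors (119 ± 63.1 against 0.0863 ± 0.107 CPM), Hoxb6, a positional homeobox gene (40.7 ± 53.2 CPM, at least 1010-fold), and Prss56, a serine protease (80.8 ± 54.9 CPM, a ratio of 3050 with an interval of 843 to 25200).

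Squamous epithelial genes fell in 8 of 20 and rose in 1 (13 and 1 adjusted over the list alone). This list passed with both correlations (camera adjusted p = 3.12e-09 and adjusted p = 0.0418 with an estimated correlation). The member that rose was Krt4, a keratin of non-cornified epithelium (296 ± 468 against 18.5 ± 18.5 CPM), of which the library labelled AKPT replicate 3 held 998 CPM and the other 3 held 57.8 to 67.2. Notch target genes fell in 9 of 16 and rose in 1 (10 and 2 adjusted over the list alone; camera adjusted p = 0.00011, adjusted p = 0.118 with an estimated correlation). Nrarp fell by 4.38 ± 0.34 on the log2 scale, from 122 ± 55.2 to 6.74 ± 1.03 CPM, while the ligand Dll4 rose from 1.04 ± 1.16 to 7.59 ± 3.82. Inflammatory cytokines and chemokines fell in 11 of 19 (13 adjusted over the list alone; camera adjusted p = 7.12e-08, adjusted p = 0.16 with an estimated correlation). Csf3 was at 0.28 ± 0.229 against 150 ± 172 CPM, the neutrophil chemokine Cxcl5 at 1.09 ± 0.479 against 178 ± 170 and Tnf at 6.96 ± 1.18 against 36.5 ± 18.9. YAP and fetal-like epithelial genes fell in 10 of 22 (13 adjusted over the list alone; camera adjusted p = 2.1e-06, adjusted p = 0.135 with an estimated correlation), with Clu, a chaperone of regenerating crypts, at 236 ± 289 against 3630 ± 1290 CPM. STAT3 and acute-phase genes fell in 7 of 21 and rose in 1 (8 and 2 adjusted over the list alone; camera adjusted p = 0.0104, adjusted p = 0.448 with an estimated correlation), with haptoglobin, Hp, at 1.34 ± 0.811 against 575 ± 590 CPM.

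Of 18458 genes, edgeR called 1382 higher and 1236 lower. Of these 1803 had no overlap between the groups, and of all genes 2919, where chance gives 1.59% of the genes tested. The labelled sex differed, since all KPN and 2 AKPT cultures were labelled male: only the male AKPT cultures gave 1389 calls, and sex as a covariate 1559. Leaving out AKPT culture 1, 2 or 4 gave 1567, 1582 or 1597 calls.

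AKPS organoids (n = 2) were compared with the same KPN cultures (n = 5), so the calls of these comparisons share controls and were not set against each other. Krt5 had 3 counts in the AKPS cultures and 430 ± 380 CPM in the KPN cultures, a ratio of 4740 (1620 to 23000). Smoc2 rose by 10.98 ± 0.86 on the log2 scale to 541 ± 437 CPM (edgeR adjusted p = 1.49e-06). Smad4, deleted by design, fell by 2.69 ± 0.26 (adjusted p = 2.12e-05) and was the only called member among 17 TGF-beta ligands and receptors (3 adjusted over the list alone; camera adjusted p = 0.000838, adjusted p = 0.406 with an estimated correlation). Integrin beta 3, Itgb3, averaged 16 ± 7.75 CPM in KPN cultures and had no count in AKPS cultures, at least 171-fold lower.

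Paneth cell genes rose in 5 of 15 (5 adjusted over the list alone; camera adjusted p = 3.53e-05, adjusted p = 0.406 with an estimated correlation), with Pla2g2a at 302 ± 308 CPM and Lyz1 at 17.5 ± 21.1. Their median was 2.00, or 1.73 with 4 members at their bound. Stem cell genes rose in 3 of 19 and fell in 1 (5 and 1 adjusted over the list alone; camera adjusted p = 1.68e-06, adjusted p = 0.156 with an estimated correlation). WNT target genes rose in 4 of 21 (5 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.00184, adjusted p = 0.55 with an estimated correlation). Rnf43, a brake on WNT receptors, was at 299 ± 147 against 43.3 ± 25.2 CPM. Goblet cell genes rose in 2 of 17 (6 adjusted over the list alone; camera adjusted p = 0.000552, adjusted p = 0.406 with an estimated correlation). Enteroendocrine cell genes rose in 2 of 18 (7 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.00375, adjusted p = 0.42 with an estimated correlation). Examples were the mucin-type transferase Galnt12 (75.9 ± 6.90 against 9.10 ± 9.95 CPM) and Reg4 (236 ± 292 against 1.72 ± 3.06). Squamous epithelial genes fell in 4 of 20 (9 lower and 2 higher adjusted over the list alone; camera adjusted p = 6.72e-07, adjusted p = 0.104 with an estimated correlation). Notch target genes fell in 4 of 16 (8 lower and 1 higher adjusted over the list alone; camera adjusted p = 1.39e-05, adjusted p = 0.104 with an estimated correlation), with Nrarp at 10.7 ± 2.71 against 122 ± 55.2 CPM.

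Inflammatory cytokines and chemokines fell in 4 of 19 (6 adjusted over the list alone; camera adjusted p = 6.72e-07, adjusted p = 0.328 with an estimated correlation), with Cxcl1, a neutrophil chemokine, at 3.11 ± 1.28 against 53.7 ± 35.3 CPM. STAT3 and acute-phase genes fell in 1 of 21 (2 adjusted over the list alone; camera adjusted p = 0.0146, adjusted p = 0.495 with an estimated correlation). Of 22 p53 target genes, which include Trp53, 2 fell (2 adjusted over the list alone; camera adjusted p = 0.0204, adjusted p = 0.406 with an estimated correlation). The called members were Hp (0.874 ± 0.229 against 575 ± 590 CPM) and, among p53 targets, Ddit4l and Phlda3 (12.5 ± 0.224 against 70.6 ± 15.8). Tgfb1 was at 35.2 ± 24.9 CPM and not called (adjusted p = 0.205). Over all genes edgeR called 365 higher and 181 lower, and DESeq2 578 and 672. Without AKPS culture 1 the count was 113, without KPN culture 5 it was 853 and in a fit of only these groups 80.

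The AKPS against KPN difference was then compared between tumours and organoids. They share no libraries but may share lines, which the organoid labels do not name. Of 17643 genes tested in both, 1289 were higher in tumours and 353 in organoids, and 184 in both, where independent lists would share 25.8 (Fisher's exact test, 2-sided p = 2.13e-115). Lower in tumours were 1029 genes and in organoids 181, with 113 in both against 10.6 for independent lists (Fisher's exact test, p = 1.47e-93). In opposite directions 2 genes were called. Among genes called in both were Smoc2, Pla2g2a and Ascl2 (higher) and Krt5, Krt6a, Krt16 and Nrarp (lower). Genes are not independent replicates, and AKPS was represented by 1 line in the tumours. Line differences alone could thus exceed the overlap of independent lists. For the origin comparison, with 1 gene called in tumours and 0 in organoids by edgeR, no gene was shared. By DESeq2 192 genes were higher in tumours and 23 in organoids, with 1 shared against 0.268 for independent lists (Fisher's exact test, p = 0.237), and none of the lower genes was shared.

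AKPT and AKPS organoids carry different floxed genes of the TGF-beta pathway, Tgfbr1 and Smad4. Pmepa1, a TGF-beta-induced gene that limits the pathway (ENSMUSG00000038400, chromosome 2, 173224458 to 173276533), fell in AKPT cultures (n = 4) to 6.51 ± 1.17 from 121 ± 60.5 CPM in AKPS cultures (n = 2), a log2 difference of -4.36 ± 0.74 (edgeR adjusted p = 0.0349). Lamb3, a chain of the basement-membrane laminin 332, was at 79.1 ± 4.29 against 299 ± 36.8 CPM (log2 -2.04 ± 0.31, adjusted p = 0.0129), and Arhgap40, which encodes a Rho GTPase-activating protein, at 5.74 ± 1.66 against 28.7 ± 3.17. Smad4 was the only gene that rose (log2 2.67 ± 0.27, adjusted p = 0.000144) and the only called member of 17 TGF-beta ligands and receptors (1 adjusted over the list alone; camera adjusted p = 0.0361, adjusted p = 0.752 with an estimated correlation). The largest fall was in a further identifier of Myl12b, a myosin light chain, at 0.115 ± 0.108 against 13.3 ± 3.29 CPM, uncertain because it overlaps the main Myl12b entry.

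None of the 22 YAP and fetal-like epithelial genes was called (6 lower adjusted over the list alone; camera adjusted p = 7.3e-12, adjusted p = 0.0779 with an estimated correlation), with Krt19 at 737 ± 130 against 1710 ± 942 CPM. Paneth cell genes, with none of 15 called and 7 higher adjusted over the list alone, had a median of 3.51, or 2.95 with 2 at their bound (camera adjusted p = 7.91e-08; adjusted p = 0.227 with an estimated correlation). Enteroendocrine cell genes (median 1.33, camera adjusted p = 0.0174; adjusted p = 0.752 with an estimated correlation; 0 called adjusted over the list alone) and general epithelial genes (-0.54, 0.00147; adjusted p = 0.64 with an estimated correlation; 2 lower adjusted over the list alone) had no called member. Krt8, a simple-epithelial keratin, was at 631 ± 30.7 against 2040 ± 1110 CPM. In total edgeR called 1 gene higher and 6 lower with 1245 at an unadjusted p under 0.05, and DESeq2 called 69. Only the male AKPT cultures left 1 call, sex as a covariate 3, and a fit without AKPT culture 1 or without culture 2 left 3 each.

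AKPT organoids (n = 4) were set against Apc organoids (n = 2) to measure what the further alleles add. Targets of p53 fell: Ccng1, an inhibitor-like cyclin (ENSMUSG00000020326, chromosome 11, 40748552 to 40755311), was at 55.0 ± 9.71 against 928 ± 145 CPM (log2 -4.07 ± 0.43, edgeR adjusted p = 0.000278), and Mdm2, which degrades p53, at 67.5 ± 4.17 against 206 ± 21.1 (log2 -1.60 ± 0.22, adjusted p = 0.00206). Of 22 p53 target genes, which include Trp53, 11 fell and none rose (18 adjusted over the list alone), and the list passed with both correlations (camera adjusted p = 4.8e-52 and adjusted p = 2.69e-06 with an estimated correlation). Trp53 itself, at 29.9 ± 40.9 against 223 ± 8.03 CPM, was not called (adjusted p = 0.119) with the library labelled AKPT replicate 3 included. Spry4, a feedback inhibitor of the RAS and MAPK pathway, rose from 2.62 ± 1.29 to 81.2 ± 30.0 CPM (log2 4.95 ± 0.78, adjusted p = 0.00518). It was the only called member of 18 MAPK output genes (7 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.0196, adjusted p = 0.492 with an estimated correlation). The antisense transcript Evx1os rose as well and is uncertain because strand was not stated.

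Clu, called alone among 22 YAP and fetal-like epithelial genes, fell from 4380 ± 3610 to 236 ± 289 CPM (4 lower adjusted over the list alone; camera adjusted p = 3.69e-08, adjusted p = 0.177 with an estimated correlation). WNT target genes had no called member, adjusted over the list alone included (median 1.05, camera adjusted p = 0.0236; adjusted p = 0.801 with an estimated correlation), with Nkd1 at 772 ± 324 against 154 ± 139 CPM. Rdx, which links actin to the membrane, rose from 5.55 ± 1.37 to 108 ± 49.1 CPM. Ano3, an anoctamin, averaged 37.7 ± 10.5 CPM in Apc cultures and had no count in AKPT cultures, at least 768-fold lower. Counting all genes, edgeR called 11 higher and 71 lower, and DESeq2 232 and 169. Without AKPT culture 1, 2 or 4 the count was 40, 38 or 45, without Apc culture 2 it was 30, with sex as a covariate 39, and with only the female AKPT cultures 3.

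AKP organoids (n = 2) and AK organoids (n = 3), both from colon tumours, differ by the Trp53 allele and by the second Apc allele. The p53 targets Zmat3, an RNA-binding protein, and Ccng1 fell, Zmat3 (ENSMUSG00000027663, chromosome 3, 32334792 to 32366014) from 409 ± 59.8 to 73.4 ± 24.4 CPM (log2 -2.64 ± 0.35, edgeR adjusted p = 0.00567) and Ccng1 from 905 ± 258 to 127 ± 114 (log2 -3.00 ± 0.52, adjusted p = 0.0274). Of 22 p53 target genes 7 fell (19 adjusted over the list alone), and the list passed with both correlations (camera adjusted p = 5.78e-33 and adjusted p = 3.68e-05 with an estimated correlation). Cbx2, a Polycomb protein, rose from 6.65 ± 1.82 to 30.3 ± 7.48 CPM (log2 2.02 ± 0.36, adjusted p = 0.0349). Lif was at 16.1 ± 5.81 against 86.8 ± 30.9 CPM and Il11 at 0.194 ± 0.0256 against 1.91 ± 1.52, neither called (adjusted p = 0.165 and 0.123). The AK cultures held some Col1a1 as well, 8.58 ± 7.07 CPM, and culture 3 had the least of both (1.13 CPM of Col1a1 and 0.301 of Il11).

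No member of the next lists was called. Proliferation genes had a median of 1.62 (22 of 24 higher adjusted over the list alone; camera adjusted p = 2.91e-19, adjusted p = 0.206 with an estimated correlation), with Top2a at 644 ± 396 against 170 ± 16.5 CPM. YAP and fetal-like epithelial genes had a median of -1.12 (3 lower adjusted over the list alone; camera adjusted p = 5.21e-07, adjusted p = 0.166 with an estimated correlation), with Krt19 at 1270 ± 71.1 against 3380 ± 298 CPM. TGF-beta target genes (median -0.64, camera adjusted p = 0.00365; adjusted p = 0.372 with an estimated correlation; 2 lower adjusted over the list alone) included Ccn2, a matricellular protein, at 237 ± 189 against 1530 ± 867 CPM. General epithelial genes (-1.01, 0.00213; adjusted p = 0.366 with an estimated correlation; 2 lower adjusted over the list alone) and colon regional genes (-2.01, 0.00564; adjusted p = 0.239 with an estimated correlation; 1 lower adjusted over the list alone) lay lower too, with the carbonic anhydrase Car1 at 18.2 ± 17.5 against 649 ± 477 CPM. Altogether edgeR called 7 genes higher and 16 lower, and DESeq2 257 and 309. The edgeR count was 1 with sex as a covariate and 4, 13 or 6 without AK culture 1, 2 or 3.

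AKPT primary tumours (n = 2) were set against AKPT organoids (n = 4) to separate what the whole tumour holds from the epithelium in culture. Collagen genes led: Col1a1 was at 2380 ± 2800 against 0.75 ± 0.223 CPM (log2 11.65 ± 0.98, edgeR adjusted p = 0.0018), and Col3a1 (ENSMUSG00000026043, chromosome 1, 45311538 to 45349706) at 2520 ± 3090 CPM with no count in the organoids, at least 50600-fold. Il11 rose from 0.35 ± 0.222 to 48.2 ± 24.8 CPM (log2 7.15 ± 0.56, adjusted p = 0.00162). Il6 reached 19.3 ± 22.8 CPM against 1 count in the organoids, a ratio of 1160 (208 to 45800), and Osm 3.07 ± 2.66 CPM against 1 count, a ratio of 186 (33.4 to 7350). Lif rose from 10.3 ± 2.92 to 33.7 ± 28.8 CPM (log2 1.78 ± 0.49, adjusted p = 0.0412) and Tgfb1 from 20.3 ± 7.28 to 70.3 ± 55.6 (log2 1.87 ± 0.50, adjusted p = 0.0374). The primary tumours differed from each other, with Col1a1 at 404 and 4360 CPM.

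**Figure D3:**
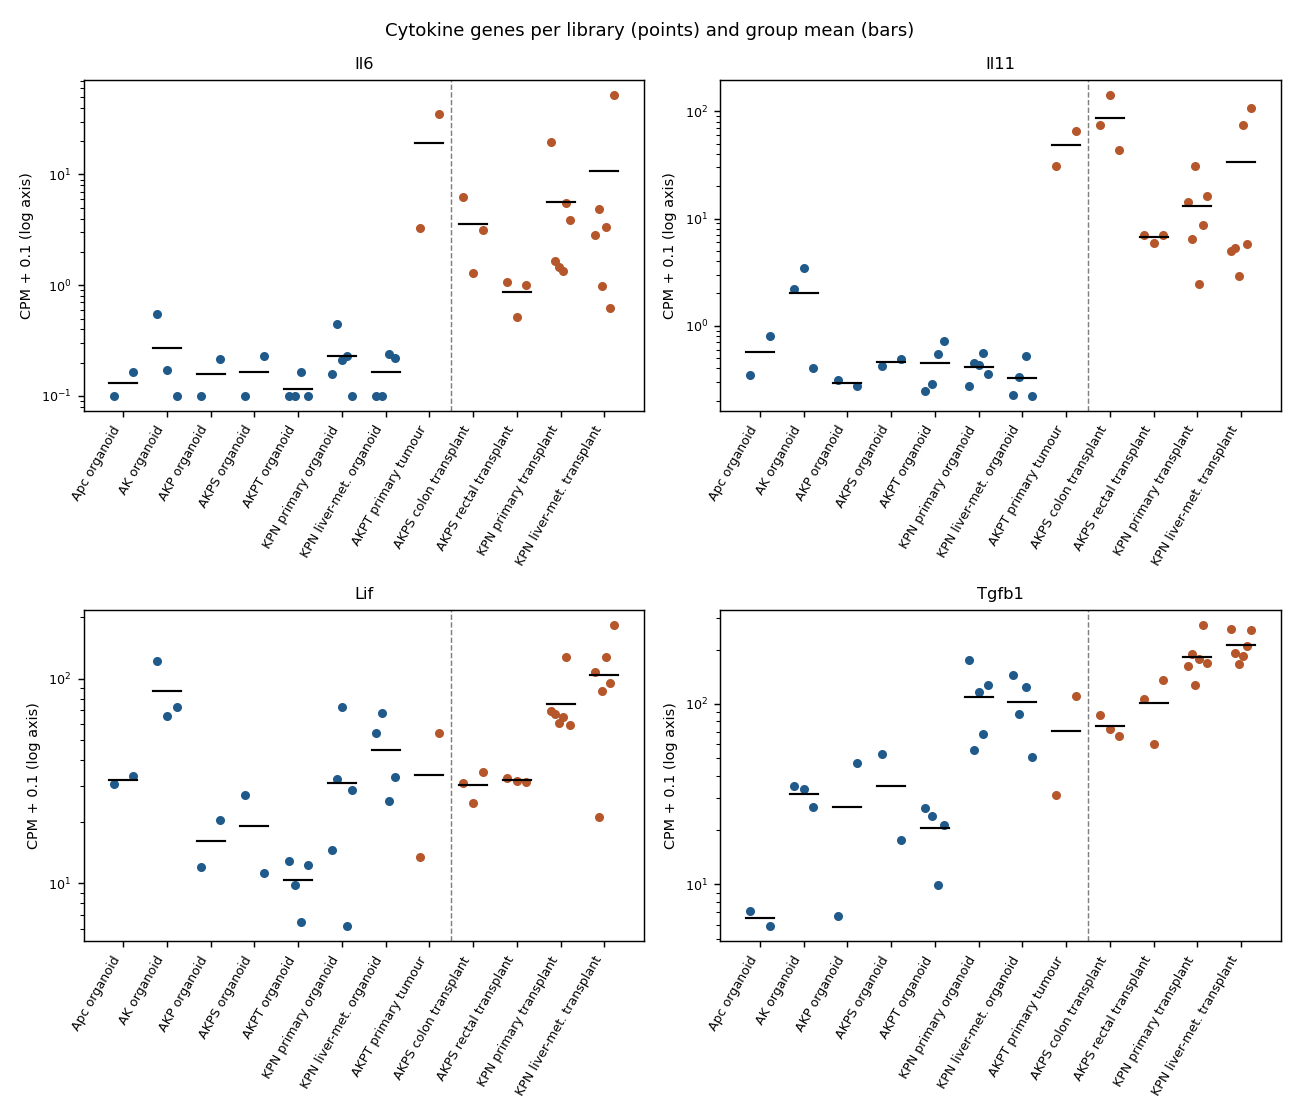
Il6, Il11, Lif and Tgfb1 as CPM + 0.1 (log axes) in every library, with bars at the group means; left of the dashed line lies the organoid table with the AKPT primary tumours, right the tumour table, blue marks organoids and orange marks tumours. Il11 was at 30.6 and 65.7 CPM in the AKPT primary tumours and at most 3.33 in any organoid library.

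Among stromal and immune lists, 22 of 24 fibroblast genes rose (22 adjusted over the list alone; camera adjusted p = 4.22e-18, adjusted p = 0.214 with an estimated correlation). So did 14 of 15 smooth muscle genes (15 adjusted over the list alone; camera adjusted p = 1.49e-12, adjusted p = 0.155 with an estimated correlation). Macrophage and monocyte genes rose in 17 of 20 (18 adjusted over the list alone; camera adjusted p = 8.19e-15, adjusted p = 0.234 with an estimated correlation). Endothelial genes rose in 12 of 19 and fell in 1 (14 and 2 adjusted over the list alone; camera adjusted p = 4.5e-13, adjusted p = 0.173 with an estimated correlation). T and NK cell genes rose in 18 of 20 (18 higher and 1 lower adjusted over the list alone; camera adjusted p = 1.33e-13, adjusted p = 0.165 with an estimated correlation). B and plasma cell genes rose in 17 of 18 (18 adjusted over the list alone; camera adjusted p = 2.94e-12, adjusted p = 0.089 with an estimated correlation). Examples were Dcn, a matrix proteoglycan (538 ± 460 against 0.0842 ± 0.0671 CPM), Myh11 of smooth muscle (146 ± 155 against 0.378 ± 0.126), Plvap of vessels (106 ± 22.3 against 0.487 ± 0.223) and Jchain of plasma cells (637 ± 595 against 0.267 ± 0.376). C1qa of macrophages reached 210 ± 202 CPM against 1 count, a ratio of 12700 (2280 to 501000). The endothelial list's lowered member was Prox1, a lymphatic factor that intestinal tumour epithelium also expresses (88.9 ± 33.2 against 544 ± 245 CPM). With members that had no count in a group at their bound, the list medians were 9.83 for fibroblasts, 7.34 for smooth muscle, 4.30 for vessels, 8.81 for macrophages, 6.20 for T and NK cells and 5.55 for B and plasma cells.

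Signalling lists changed too. Genes that fibroblasts express in response to TGF-beta rose in 16 of 20 (18 adjusted over the list alone; camera adjusted p = 1.31e-10, adjusted p = 0.28 with an estimated correlation). The gp130 cytokines and receptors rose in 9 of 14 (9 adjusted over the list alone; camera adjusted p = 0.000385, adjusted p = 0.419 with an estimated correlation). STAT3 and acute-phase genes rose in 14 of 22 (15 adjusted over the list alone; camera adjusted p = 1.23e-06, adjusted p = 0.175 with an estimated correlation). TGF-beta target genes rose in 10 of 20 and fell in 1 (10 and 1 adjusted over the list alone; camera adjusted p = 6.07e-05, adjusted p = 0.165 with an estimated correlation), with Pmepa1 at 343 ± 134 against 6.51 ± 1.17 CPM (log2 5.83 ± 0.25, adjusted p = 0.00133). Bcl3, a STAT3-induced cofactor, rose from 32.6 ± 3.85 to 91.6 ± 10.8 CPM, and Reg3b, an antimicrobial lectin, from 0.664 ± 0.735 to 3130 ± 3020. Interferon-response genes rose in 19 of 23 (21 adjusted over the list alone; camera adjusted p = 3.21e-13, adjusted p = 0.155 with an estimated correlation). MHC and antigen-presentation genes rose in 18 of 18 (18 adjusted over the list alone; camera adjusted p = 7.56e-21, adjusted p = 0.155 with an estimated correlation), with the class II gene H2-Aa at 255 ± 43.1 against 0.0716 ± 0.106 CPM, uncertain because of its paralogs.

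Epithelial, WNT and MAPK lists changed in both directions. Small-intestinal enterocyte genes rose in 20 of 22 (22 adjusted over the list alone; camera adjusted p = 3.45e-10, adjusted p = 0.303 with an estimated correlation). Tuft cell genes rose in 10 of 15 (11 higher and 1 lower adjusted over the list alone; camera adjusted p = 1.87e-06, adjusted p = 0.155 with an estimated correlation). Goblet cell genes rose in 9 of 18 (13 adjusted over the list alone; camera adjusted p = 0.000301, adjusted p = 0.328 with an estimated correlation). The examples were lactase, Lct (130 ± 131 against 0.0658 ± 0.0517 CPM), the tuft cell kinase Dclk1 (55.5 ± 31.6 against 0.721 ± 0.591) and the goblet cell lectin Zg16 (974 ± 1150 against 1.42 ± 0.892). WNT target genes fell in 10 of 21 (11 lower and 1 higher adjusted over the list alone; camera adjusted p = 2.12e-06, adjusted p = 0.269 with an estimated correlation). Proliferation genes fell in 13 of 24 (15 adjusted over the list alone; camera adjusted p = 1.94e-08, adjusted p = 0.328 with an estimated correlation). Cholesterol synthesis genes fell in 7 of 23 (10 adjusted over the list alone; camera adjusted p = 4.1e-07, adjusted p = 0.361 with an estimated correlation). Stem cell genes fell in 6 of 19 and rose in 1 (6 and 1 adjusted over the list alone; camera adjusted p = 0.00206, adjusted p = 0.361 with an estimated correlation). MAPK output genes fell in 6 of 18 and rose in 1 (7 and 1 adjusted over the list alone; camera adjusted p = 0.00181, adjusted p = 0.155 with an estimated correlation). Tnfrsf19, a WNT-induced receptor, fell from 560 ± 170 to 77.1 ± 42.4 CPM, Top2a from 884 ± 279 to 208 ± 26.0, Pcsk9, which degrades the LDL receptor, from 503 ± 90.6 to 61.8 ± 18.2, and the phosphatase Dusp4 from 317 ± 133 to 37.2 ± 8.30. The members that rose were Olfm4 (127 ± 72.8 against 2.33 ± 2.00 CPM) and Ereg, a growth factor (log2 3.77 ± 0.66, adjusted p = 0.00981).

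Of 17892 genes, edgeR called 3149 higher and 1289 lower. Of these 4406 had no overlap between the groups, and of all genes 8978, where chance gives 13.3% of the genes tested. The primary tumours were labelled female and 2 of the organoid cultures male: with only the female organoids edgeR called 0 genes, with 4309 at an unadjusted p under 0.05 and a lowest adjusted p of 0.0654 in 4 libraries. Without organoid culture 1 or 2 the counts were 2673 and 2686.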

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

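Each value of a gene named in the text, of a described list and of the total counts was compared with the other libraries of its group, in groups of 4 to 6 libraries. A library was singled out when its gap to the nearest other, over the range of the group, passed Dixon's 95% value. Of 310 group values tested 36 passed, and chance gives about 1 in 20. Genes and lists with a group mean under 1 were not tested. The tests of the 2 patterns weighed here were chosen after the results were seen.

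The library labelled AKPT organoid 3 had 91.3 CPM of Trp53, far from the other 3 at 8.75 to 10.7. If it were a mislabelled culture with working p53, its p53 target genes should lie near the Apc and AK organoids (6.90 to 7.49 as mean log2 of CPM + 1), but they lay at 4.64, beside the other AKPT organoids at 4.72 to 4.79. If cells with working p53 were mixed in, the 11 p53 targets called in AKPT against Apc organoids without this library, Trp53 aside, should lie as far towards the Apc organoids as Trp53 does (38.3% of the way), but their median place was 0.193% (range -5.08 to 28.8). Both technical explanations were argued against by these values. A transcript without p53 activity stays open, since exons are not resolved in the counts, and no biological explanation was tested.

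The KPN liver-metastasis organoids 1, 2 and 4 and KPN small-intestinal organoid 2, labelled male, had at most 1 count of Ddx3y, a Y-linked gene, where the libraries labelled female had at most 2 and the 11 other male organoid libraries 12.8 to 127 CPM. Low depth was argued against, because the lowest of those levels would give at least 200 counts in each of the 4. Cultures from female mice that express Xist were argued against too, since Xist reached at most 1.1 CPM in the 4 libraries against 636 to 2130 in the 9 labelled female. Loss of the Y chromosome in culture or tumour and a female culture without Xist were not told apart. No biological explanation was tested.

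AKPT organoid 3 also stood apart from the other 3 AKPT organoids in Prss56 (2.51 against 93.1 to 131 CPM), Cd44 (314 against 208 to 222), Krt4 (998 against 57.8 to 67.2), Pmepa1 (4.78 against 6.94 to 7.26), Ccng1 (69.5 against 48.8 to 51.2) and Nkd1 (300 against 822 to 1010). The WNT target genes as a list were at 6.54 there against 7.57 to 7.78. AKPT organoid 4 was high in Ereg (7.44 against 1.51 to 1.89 CPM), and AKPT organoid 1 had the lowest total count of its group, in units of 1e6 counts 13.42 against 15.85 to 16.12.

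KPN small-intestinal organoid 5 had the lowest total count of its group (7.82 against 15.49 to 18.17 in the same unit), with Notch1 at 6.65 CPM against 184 to 332 and Rnf43 at 6.14 against 38.2 to 69.7. It was also low in the intestinal stem cell genes (3.75 against 5.56 to 5.85), tuft cell genes (0.91 against 1.5 to 1.62) and cholesterol synthesis genes (6.53 against 7.27 to 7.46). KPN small-intestinal organoid 3 was high in interferon-response genes (5.43 against 1.27 to 2.36) and in MHC and antigen-presentation genes (4.70 against 2.80 to 2.97). KPN small-intestinal organoid 2 was far from its group in Galnt12 (26.8 against 3.47 to 5.46 CPM) and Krt6a (119 against 432 to 682), and organoid 1 in Reg4 (7.16 against 0.116 to 0.968). KPN liver-metastasis organoid 4 lay apart in inflammatory cytokines and chemokines (3.21 against 3.09 to 3.1) and in macrophage and monocyte genes (1.1 against 1.41 to 1.46).

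Among KPN tumours of liver-metastasis origin, Il6 was at 52.2 CPM in tumour 6 against 0.528 to 4.79, and Lif at 21.1 in tumour 2 against 87.4 to 182. The YAP and fetal-like epithelial genes were low in tumour 2 (7.10 against 8.16 to 8.47) and the STAT3 and acute-phase genes in tumour 3 (3.75 against 4.94 to 5.43). Tumour 5 was high in enteroendocrine cell genes (2.41 against 0.76 to 1.3) and small-intestinal enterocyte genes (2.81 against 0.65 to 1.14). Among those of small-intestinal origin, tumour 5 was high in Lif (128 against 59.3 to 69.2 CPM) and Jag1 (288 against 113 to 140), tumour 6 low in Id2 (67.8 against 124 to 152) and tumour 3 low in Wt1 (0.682 against 8.01 to 20.3). Tumour 3 was also high in colon regional genes (4.72 against 0.97 to 1.43), goblet cell genes (6.36 against 1.29 to 2.33) and enteroendocrine cell genes (2.06 against 0.83 to 0.97). The origin difference of Mcpt8 differed between the 2 KPN lines by 5.8 on the log2 scale in the test of the product of origin and line.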

How the results depend on the processing

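Groups held 2 to 6 libraries, AKPS tumours came from 1 line and KPN tumours, RKAC.2f aside, from 2. Depth was 7815940 to 24765688 counts, so low genes were measured poorly in shallow libraries. Of 1875 values of the 120 named called genes under an alternative, 1622 kept direction and call, 253 kept direction and lost the call, and none turned. Of 1099 values of the 71 named genes that were not called, 1018 stayed the same, 30 passed the test and 51 changed sign without a call. The largest losses of named calls in each comparison were with only the female AKPT organoids against the primary tumours (27 of 27), the replicate block in AKPS against KPN organoids (17 of 17) and in AKPT against AKPS organoids (5 of 5), only the female AKPT organoids against Apc organoids (5 of 7), only the male AKPT organoids against KPN organoids (6 of 25) and without AKPS colon tumour 3 in AKPS against KPN tumours (9 of 36). In AKP against AK organoids all 3 were lost under each of the replicate block, the sex covariate, the fit of only these groups and the fit without AKP organoid 2. Unless stated, the cause was not tested.

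The main counts of called genes were 1 for the origin in KPN tumours, 2537 for AKPS against KPN tumours, 0 for the site, 0 for the origin in KPN organoids, 2618 for AKPT against KPN, 546 for AKPS against KPN organoids, 7 for AKPT against AKPS, 82 for AKPT against Apc, 23 for AKP against AK and 4438 for primary tumours against organoids. For the product of origin and line it was 1, and the overlaps held 113 lower genes for AKPS against KPN and 0 higher genes for the origin. Counts that moved by over 1.5 times follow. With DESeq2 they were 426 for the origin in KPN tumours, 36 for the origin in KPN organoids, 1250 for AKPS against KPN organoids, 69 for AKPT against AKPS, 401 for AKPT against Apc, 566 for AKP against AK and 283 for the product of origin and line, and the overlaps held 351 lower genes for AKPS against KPN and 1 higher gene for the origin. Without a low-count filter 2 genes were called for the origin in KPN tumours, and with the filter at 5 CPM 1722 for AKPT against KPN and 2789 for primary tumours against organoids, with fewer genes tested. Leaving out the libraries that stood apart, chosen after seeing the data, gave 15 for the origin in KPN tumours and 1562 for AKPS against KPN tumours.

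For the origin in KPN tumours the count was 0 in each line alone, with 12 libraries and no line term, and in a fit of all 18 libraries without it. Against RKAC13.1e tumours alone AKPS tumours gave 1489. Fits of only the 2 groups gave 4130 for AKPS against KPN tumours, 1 for the site, 1424 for AKPT against KPN, 80 for AKPS against KPN organoids, 2 for AKPT against AKPS and 264 for AKPT against Apc. Sex as a covariate gave 1559 for AKPT against KPN, 3 for AKPT against AKPS, 39 for AKPT against Apc and 1 for AKP against AK. Only male AKPT cultures gave 1389 against KPN and 1 against AKPS, and only female ones 3 against Apc and 0 against the primary tumours, with fewer samples.

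Replicate numbers did not pair the libraries, since same-number correlations ran from -0.39 to 0.51 and no set of at least 3 pairs was all above 0.1. A block on that number gave 0 for the origin in KPN tumours, 4517 for AKPS against KPN tumours, 1424 for AKPT against KPN, 0 for AKPS against KPN organoids, 0 for AKPT against AKPS, 405 for AKPT against Apc, 12 for AKP against AK and 2650 for primary tumours against organoids.

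Leaving out each library in turn gave 0 to 228 for the origin in KPN tumours (228 without liver-metastasis tumour 3), 1085 to 3038 for AKPS against KPN tumours (1085 without AKPS colon tumour 3), 0 to 7 for the site (7 without rectal tumour 2), 0 to 14 for the origin in organoids (14 without liver-metastasis organoid 3) and 1567 to 3147 for AKPT against KPN. The ranges were 113 to 853 for AKPS against KPN organoids (113 without AKPS organoid 1), 3 to 9 for AKPT against AKPS, 30 to 100 for AKPT against Apc (30 without Apc organoid 2), 1 to 13 for AKP against AK and 2673 to 4684 for primary tumours against organoids. A group left with 1 library was assumed to vary like the others.

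Of the 90 described results of lists, 85 lost their call with an estimated correlation and 44 with fry. The main test called 9, 22, 20, 3, 13, 16, 12, 8, 15 and 31 lists, in the order of the main counts above. With an estimated correlation 0, 2, 0, 0, 1, 0, 0, 1, 1 and 0 lists passed, in the same order. With fry the counts were 1, 12, 0, 0, 14, 3, 0, 1, 7 and 28, again in the order of the main counts.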

Other observations

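The KPN lines RKAC13.1e and RKAC3.2f differed from each other. This comparison, the counts over splits and the tests of the neighbours of Trp53 were chosen after the results were seen, with the comparison of lines added after seeing the data. In tumours of RKAC13.1e (n = 6) against RKAC3.2f (n = 5), with the origin as a covariate, Gp2, a glycoprotein of M cells, rose to 185 from 0.0847 CPM (edgeR adjusted p = 2.2e-06). Bpifb1, a secreted protein of airway and gastric glands, rose to 236 from 0.0312 CPM, and Ptges, a prostaglandin E synthase, to 449 from 40.3. Krt5 was at 1310 against 36.1 CPM and Notch1 at 191 against 67.1, both called. Krt14 was at 849 against 450 CPM and not called (adjusted p = 0.25). Goblet cell genes rose in 6 of 13, with Muc2 at 423 against 3.07 CPM (camera adjusted p = 3.69e-06; adjusted p = 0.741 with an estimated correlation). The level of the goblet cell genes (mean log2 of CPM + 1) was 6.36 in small-intestinal-origin tumour 3 and 4.28 and 6.67 in liver-metastasis-origin tumours 4 and 5. It was 2.22 to 2.33 in the other 3 tumours of RKAC13.1e, against 1.12 to 2.11 in RKAC3.2f. The colon regional genes stood at 4.72, 2.57 and 4.49 in those 3 tumours, against 0.97 to 1.43 in RKAC3.2f. Intestinal stem cell genes rose in 6 of 19, with Lgr5 at 57.1 against 20.7 CPM, and passed with both correlations (camera adjusted p = 5.3e-05; adjusted p = 0.0458 with an estimated correlation).

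WNT target genes rose in 8 of 21 and fell in 1 (camera adjusted p = 3.63e-07; adjusted p = 0.0657 with an estimated correlation), with Axin2, a feedback inhibitor of WNT signals, at 61.8 against 10.7 CPM. Squamous epithelial genes rose in 4 of 18 and fell in 1 (camera adjusted p = 4.85e-06; adjusted p = 0.0657 with an estimated correlation). Macrophage and monocyte genes had 1 of 23 lower (camera adjusted p = 9.61e-05; adjusted p = 0.913 with an estimated correlation). Ly6c1 fell to 43.1 from 159 CPM, together with its neighbours on chromosome 15, where 46 of the 109 genes tested within 2.5 Mb were lower and 6 higher. In all 676 genes were higher and 293 lower of 17805.

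Whether groupings of the same libraries other than the labelled one call as many genes was tested by splitting them in other ways. For the KPN lines 1 of 100 splits, the labelled one, reached its 969 genes, and the next highest called 297. For the origin in KPN tumours 1 of 100 splits reached the 1 gene and the others called 0. For AKPS against KPN tumours 1 of 84 splits reached 2537, and the next highest called 813. For AKPT against KPN organoids 1 of 100 splits reached 2618, with 1209 in the next. For the site all 10 splits reached the 0 genes of the labelled one and the highest called 2, too few splits for a share under 0.05. For the origin in KPN organoids the labelled split called 0, which all 100 splits reach by necessity, so their number says nothing on chance. The median of the other splits was 0 and the highest called 1430, so a grouping of these cultures other than by origin can call many genes. What sets that split apart was not tested.

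The genes Atp1b2, Shbg and Sat2 lie within 50 kb downstream of Trp53 on chromosome 11 and had higher means in the 17 organoid libraries labelled with the Trp53 deletion, AKPT organoid 3 among them, than in the 5 without (log2 ratios 4.13, 3.86 and 3.43 with 0.1 CPM added). The lowest library of the deletion and the highest without it each had 1 count of Shbg (0.0645 and 0.0637 CPM), and Fxr2, the next gene on that side, overlapped (0.36). A change of the whole region or of the scaling would raise the genes on the other side as well, but the highest ratio there was 0.29 (Efnb3), a test first set up on the largest absolute ratio (Dnah2, -1.84) and then reworded to the same direction. A hypothesis is that transcription may run on past the deleted gene: in AKPT organoid 3, with Trp53 transcript but p53 targets as low as in the other AKPT organoids, all 3 genes were lower than in those (Atp1b2 1.57 against 2.01 to 3.34 CPM, Shbg 0.566 against 2.53 to 2.97, Sat2 4.71 against 11 to 16.8). That is a single library, and Atp1b2 and Shbg lie on the strand opposite to Trp53 and Sat2, where run-on transcripts would be counted only if strand was ignored, which the sources do not say, so loss of p53 activity stays open beside it.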
